A study of Rattus norvegicus with 12 samples.

How the data were processed

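Gene expression was measured in 12 intracranial tumours, each from a separate female Fischer rat per the labels. Rat 9L gliosarcoma cells carrying EGFRvIII, a truncated and constitutively active form of the epidermal growth factor receptor, formed 6 tumours, and 9L cells carrying the empty vector (EV) formed the other 6. Cells had been placed 2 mm deep in the cortex in 10 µL, and tumours were removed 3 weeks later. About 100 ng of RNA per tumour was amplified into biotinylated cRNA and hybridised to Illumina RatRef-12 bead arrays, 1 array per tumour.

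The deposited non-normalized table gives an average signal intensity per probe and array. Its values go below 0, so a background had been subtracted by the authors before deposition. The deposited detection score runs from 0 to 1 and is high for bright probes, and it was read as 1 minus a detection p. The authors' value table was read, from its values alone, as log2 after quantile normalization. Some of its values are 0, and on every array these outnumber the signals of 0 or less (5479 against 5419 on EV rat 1). The steps behind that table are not given in the sources used here. Partek is named in the submitters' processing notes, with no version. Each of the 12 columns of the value table matched its own array best among all arrays, and no pair of arrays shared more than 0.0806% equal signals.

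Starting from the intensities, limma 3.58.1 in R 4.3.3 applied neqc, which corrects background by a normal and exponential model with the negative control level inferred from the detection p, adds an offset of 16, takes log2 and quantile normalizes between arrays. Of 22523 probes, 13793 had 1 gene symbol and 8730 had none in the probe annotation used here. Probes with a detection p under 0.05 on at least 6 of 12 arrays were kept (11862), and a gene with several kept probes was represented by the one with the highest mean over all arrays. This left 11695 genes, of which 8383 had a symbol and 3312 were tested under the probe's own name. No scan date or chip position is given in the sources used here, so batches could not be sought by them. Precision is limited by the number of arrays.

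Group means were compared with lmFit and eBayes with a mean-variance trend, two-sided, at a Benjamini-Hochberg adjusted p of 0.05 over all genes tested, with 10 residual degrees of freedom. Values of single genes are given as mean ± SD (n = 6 per group) and changes as EGFRvIII minus EV ± SE on the log2 scale. For a gene detected on 0 arrays of a group, the fold is a bound computed against the floor of that group. Gene lists, 35 in all and 15 of them markers of cell types, were tested with camera at a preset correlation between genes of 0.01, adjusted over the 33 lists with at least 5 measured members. The call was repeated with an estimated correlation and with fry. Of the symbols in the lists, 575 matched by symbol, 19 through an older name and 103 had no match among the genes of the array. Differences between arrays in signal were tested by exact two-sided permutation of the group labels, and correlations by permutation. Correlations were repeated without the 2 tumours farthest from the median of a single score of the pair, which leaves few tumours within a group.

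The groups, the tests, the lists, most of the alternatives below and the rule for named genes were set before the data were examined. The rule takes Egfr and every EGFR family member or ligand past the threshold. It adds the 8 named genes with the largest rise and the 8 with the largest fall among genes whose groups overlap by at most 1 array, and up to 4 members past the threshold from each list, those with the largest change. This gave 107 genes besides Egfr. The labels number the rats 1 to 6 in both groups, but the numbers did not pair the tumours: after the group means were removed, rats of the same number correlated at -0.34 to -0.06, and 0 of 6 matched best with their own number, so no pairing was used.

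Alternatives were other background and normalization steps, the authors' log2 values, other filters, the mean of all probes of a gene, the rat number as a block, the order of the letters in the sample descriptions, array weights, other variance models, each array left out in turn, and a minimum fold. The alternatives of leaving out 2 or 3 arrays that stood apart, or adjusting for brain markers, were added only after the data had been seen. Gene order came from the reference annotation of the rat assembly GRCr8. Tested on simulated data with 50 changed genes per size among 11695 genes drawn independently, the procedure recovered 44%, 68%, 98% and 100% of genes changed by a log2 value of 0.5, 1, 2 and 4, with 5 false calls among 160. Real genes are correlated and 21.5% of them passed, so these rates may not carry over to the real data. Correlations and figures used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.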

Results

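Tumours grown in rat brain from 9L gliosarcoma cells were profiled on bead arrays, 6 carrying EGFRvIII and 6 carrying the empty vector (EV). A mean of 12143 probes (range 11720 to 12719) was detected per EV array and 11605 (range 11182 to 12040) per EGFRvIII array, a difference with an exact permutation p of 0.0346. EGFRvIII arrays were dimmer: the 75th percentile of the signal was 109 ± 8.39 against 144 ± 10.8 (SD, n = 6 each, exact permutation p = 0.00216, the smallest that 924 arrangements allow, and 0.00649 after adjustment). Correlations between arrays ranged from 0.925 to 0.985 within the EV group, from 0.954 to 0.991 within the EGFRvIII group and from 0.897 to 0.972 between groups. The first principal component held 39.0% of the variance and separated the groups.

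The comparison asked how the expression profile differed between EGFRvIII and EV tumours. The labels name 1 line per group, so the 6 rats of a group do not repeat the introduction of EGFRvIII. The tests measure spread between rats, and a difference between the lines cannot be separated from EGFRvIII. EGFRvIII tumours had far more transcript of Mmp10, a secreted matrix metalloproteinase (log2 4.95 ± 0.83 in EV and 11.02 ± 0.58 in EGFRvIII tumours, n = 6 each, 67.2-fold, or 59.6-fold with values under the detection floor raised to it), and of Il1rl1, the receptor for interleukin 33 (17.6-fold). Stc1, a secreted glycoprotein hormone, fell from 11.69 ± 0.55 to 7.67 ± 0.41 (16.2-fold lower). Hypoxia and glycolysis genes, cell cycle genes and macrophage markers were higher as groups in EGFRvIII tumours at a preset correlation between genes, and endothelial and fibroblast markers were lower. With an estimated correlation none of these lists passed (adjusted p between 0.486 and 0.850), and splits of the tumours that ignore the groups often gave as many lists (60 of 100 splits, the real one included). For Mmp10, Il1rl1 and Stc1 all 6 EGFRvIII tumours lay on 1 side of all 6 EV tumours.

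Of 11695 genes, 2519 passed the threshold (21.5%), 1299 higher and 1220 lower in EGFRvIII tumours, and 1862 of them carried a gene symbol (953 higher and 909 lower). A change of at least 2-fold was seen in 300 of the higher and 201 of the lower genes. The groups did not overlap at all for 1301 genes (11.1%), where chance gives 0.216%. Without quantile normalization, after scaling each array to the same median, 2119 genes were higher and 1097 lower and the median change of all genes moved from 0.01 to 0.10, so the balance of rises and falls depends on the scaling.

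**Figure D1:**
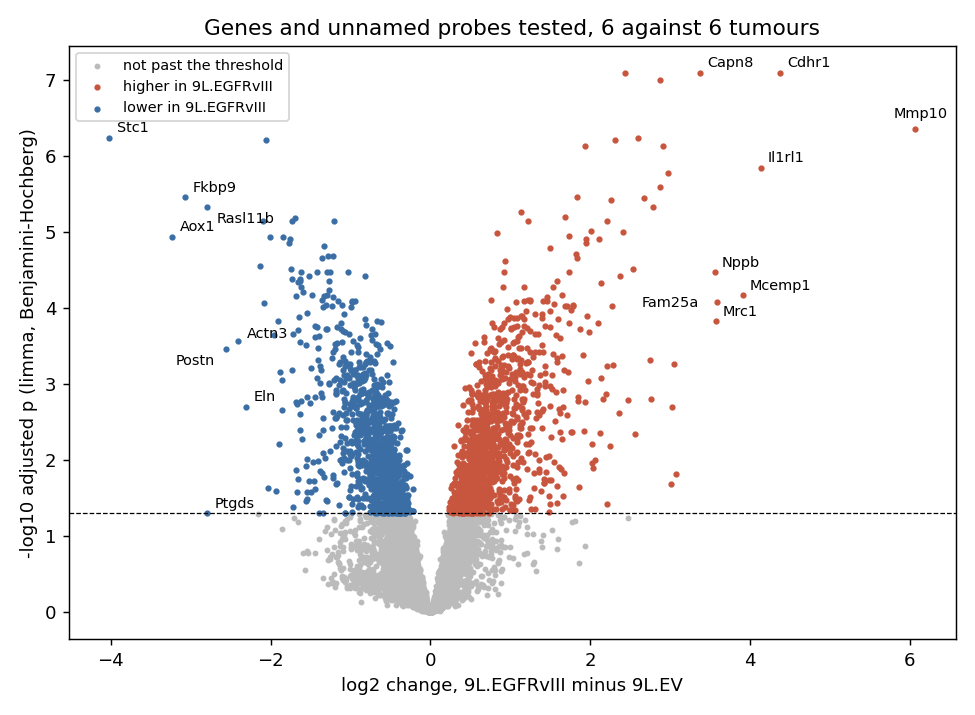
Change between groups on the log2 scale (EGFRvIII minus EV, x axis) against the adjusted p (y axis, as minus log10) for all 11695 genes, 1 point per gene. Points past the threshold are coloured by direction, and Mmp10 at 6.07 and Stc1 at -4.02 lie farthest out.

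Among the genes with the largest rise, Mmp10 changed by 6.07 ± 0.36 (adjusted p = 4.4e-07), although it was detected in only 3 of 6 EV tumours. Cdhr1, a cadherin-related protein of photoreceptors, rose 20.8-fold (4.38 ± 0.21, adjusted p = 8.0e-08), Il1rl1, detected in 4 of 6 EV tumours, by 4.14 ± 0.29 (adjusted p = 1.4e-06), and both Mcemp1, a membrane protein of mast cells and myeloid cells, and Fam25a rose from levels near background. Mcemp1 was detected in 1 of 6 EV tumours and Fam25a in 3 of 6, and with values under the detection floor raised to it they were 12.6-fold and 11.6-fold higher. Mrc1, the macrophage mannose receptor, rose 11.9-fold (3.57 ± 0.45, adjusted p = 1.5e-04). Nppb, which encodes the brain natriuretic peptide, and Capn8, a calpain protease, were detected in 0 of 6 EV and 6 of 6 EGFRvIII tumours and were at least 9.99-fold and at least 8.31-fold higher (adjusted p = 3.4e-05 and 8.0e-08).

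Among the genes with the largest fall were Stc1 (-4.02 ± 0.25, adjusted p = 5.7e-07), the aldehyde oxidase Aox1 (-3.23 ± 0.29), the endoplasmic reticulum prolyl isomerase Fkbp9 (-3.07 ± 0.24), the small GTPase Rasl11b (-2.79 ± 0.22) and the muscle actinin Actn3 (-2.41 ± 0.33). Both Postn, the matrix protein periostin (-2.55 ± 0.36, adjusted p = 3.4e-04), and Eln, elastin (-2.30 ± 0.42, adjusted p = 0.00198), also fell. Ptgds, a prostaglandin D synthase abundant in the meninges, changed by -2.79 ± 0.94 with an adjusted p of 0.0498. Its call was lost without any one of EV rats 1 to 5 or EGFRvIII rats 2 to 5, and its adjusted p reached 0.213 over the alternatives.

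**Figure D2:**
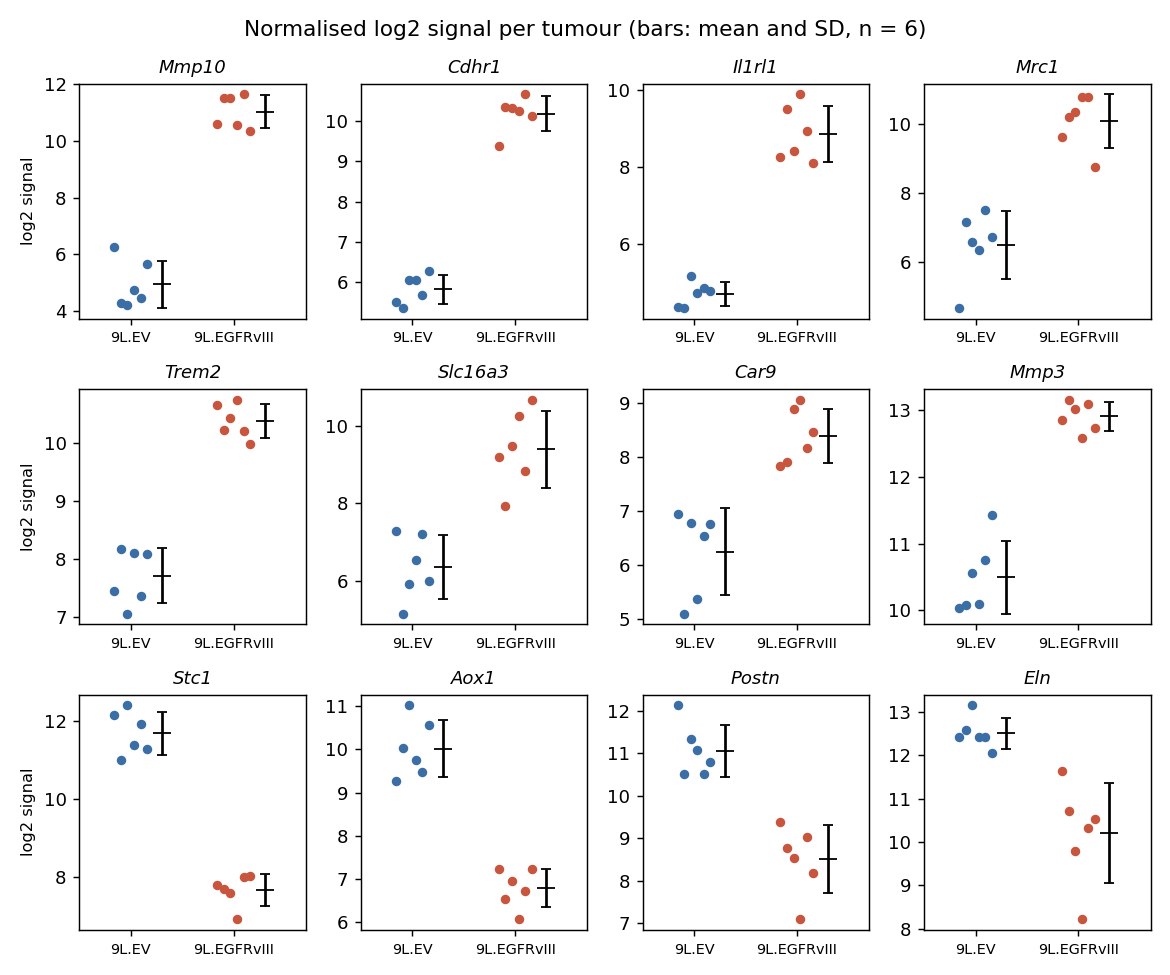
Log2 signal (y axis) of 12 of the named genes, 1 point per tumour, with bars for the mean and SD of 6 tumours per group. Mmp10 lies at 4.95 in EV and 11.02 in EGFRvIII tumours, and Stc1 at 11.69 and 7.67.

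The rat Egfr probe was detected on 0 of 12 arrays (log2 4.46 ± 0.06 in EV and 4.38 ± 0.11 in EGFRvIII tumours) and was not tested. Whether it binds the introduced transcript is not given in the sources used here, so it does not test the group labels. Hbegf, a ligand of the receptor, rose 3.78-fold (1.92 ± 0.28, adjusted p = 4.1e-04) and was the 1 gene called among 8 measured members of the EGFR family and ligand list (7 not called, list adjusted p = 0.473). Of 17 genes of MAPK output and feedback, 5 were higher, including Epha2 (1.59 ± 0.24) and Spred1 (1.45 ± 0.34), 4 were lower, including the feedback inhibitor Spry4 (-1.19 ± 0.20) and Phlda1 (-1.18 ± 0.20), and 8 were not called. Adjusted over the list alone, 6 were higher and 4 lower, and the list as a whole did not pass (median -0.06, mean 0.06, camera direction upward, adjusted p = 0.953). Immediate early genes went both ways, with Myc (1.09 ± 0.27) and Atf3 (0.78 ± 0.17) among 5 higher and Jun (-0.92 ± 0.15) the 1 lower of 16 (adjusted p = 0.397).

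Of 20 genes of hypoxia and glycolysis, 13 were higher, 1 was lower and 6 were not called; adjusted over the list alone, 14 were higher and 1 lower. The lactate transporter Slc16a3 rose 8.28-fold (3.05 ± 0.46, adjusted p = 5.4e-04), the carbonic anhydrase Car9 rose 4.41-fold (2.14 ± 0.34) and the glycolytic enzyme Eno1 rose 3.86-fold (1.95 ± 0.18), whereas Ddit4, an inhibitor of mTORC1 that stress induces, was lower (-1.39 ± 0.36). The median change of the list was 0.74 (camera adjusted p = 1.7e-06), and the adjusted p was 0.486 with an estimated correlation. Within EGFRvIII tumours the score of this list followed that of macrophage markers (r = 0.910, exact permutation p = 0.00278, adjusted 0.00833 over 15 relations, rho = 1.00). This pair was chosen after the result had been seen, and the adjustment does not cover that choice. Without the 2 tumours farthest out r was 0.994, over too few tumours to tell what it rests on. Within EV tumours r was -0.24 (exact permutation p = 0.694, rho = -0.20), and the difference between the groups was not tested. The hypoxia scores of the groups lay apart (EV up to -0.27, EGFRvIII from -0.07), so no correlation over all tumours is given. The cell cycle list rose slightly, with a median of 0.34, positive values in 26 of 26 genes, 4 called higher and 22 not called, among them the mitotic regulators Cdc20 (0.91 ± 0.20) and Kif20a (0.84 ± 0.16). Adjusted over the list alone, 3 were higher and 0 lower. Its adjusted p was 7.3e-04, and 0.850 with an estimated correlation. EV rat 2, the highest in brain markers (centred cell cycle score -0.83), and EV rat 3 (-0.32) lay lowest, with the other EV tumours at -0.06 to 0.08, and the median of the list was 0.21 without EV rat 2 and 0.13 without both. Among 13 genes of cholesterol and fatty acid synthesis 4 were higher, 9 were not called and, adjusted over the list alone, 6 were higher. Scd, a fatty acid desaturase, rose by 1.07 ± 0.19, Msmo1 by 0.81 ± 0.17 and Fdps by 0.75 ± 0.20, and the list had a median of 0.43 (adjusted p = 0.0405, and 0.850 with an estimated correlation). Its adjusted p lay between 0.0565 and 0.0786 without any one of EV rats 2 and 6 or EGFRvIII rats 2, 3 and 5. Of 19 NRF2 targets and oxidative stress genes 6 were higher, 1 was lower and 12 were not called, with the same numbers adjusted over the list alone. Heme oxygenase Hmox1 rose by 1.56 ± 0.31, the NADPH oxidase subunit Cybb by 1.44 ± 0.37 and Nqo1 by 0.78 ± 0.14, and the glutathione transferase Gsta4 was lower (-0.98 ± 0.23). The list had a median of 0.31 (adjusted p = 0.0405, and 0.486 with an estimated correlation), and its adjusted p was 0.0528, 0.0528 and 0.0565 without EGFRvIII rat 2, 3 and 5.

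Matrix genes moved in both directions. Of 28 extracellular matrix and invasion genes 5 were higher, 12 lower and 11 not called; adjusted over the list alone, 5 were higher and 13 lower. The stromelysin Mmp3 rose 5.33-fold (2.41 ± 0.21, adjusted p = 9.9e-06) and the urokinase Plau rose by 1.57 ± 0.27, while Postn and the metalloproteinase inhibitor Timp2 (-1.34 ± 0.28) fell. The list did not pass as a whole (median -0.28, adjusted p = 0.122, and 0.850 with an estimated correlation). Among neural stem cell, Notch and Id genes, Notch1 (-1.30 ± 0.14) and Prom1 (-1.34 ± 0.31) were among 4 lower, Id2 (2.29-fold) and Cd44 (1.15 ± 0.14) were the 2 higher, and the list of 12 did not pass (adjusted p = 0.464). Of 15 angiogenic factors 2 were higher, including the endothelial proteoglycan Esm1 (2.06 ± 0.50), and 2 lower (list adjusted p = 0.792). Of 14 complement genes 1 was higher (Cd55, 0.92 ± 0.22) and 2 lower, including Cfd (-1.28 ± 0.12). Adjusted over the list alone, 1 was higher and 3 lower (list adjusted p = 0.397).

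Markers of microglia and macrophages were higher: 8 of 20 passed, 0 were lower, 12 were not called, and adjusted over the list alone 10 were higher and 1 lower. Besides Mrc1, the lipid receptor Trem2 rose 6.37-fold (2.67 ± 0.21, adjusted p = 3.5e-06), the Fc receptor Fcgr2b by 2.12 ± 0.44 and arginase Arg1 by 2.03 ± 0.50. The list had a median of 0.94 (adjusted p = 7.3e-04, and 0.850 with an estimated correlation). In EV rat 3 the mean of these markers was 6.74, against 7.96 in the other 5 EV tumours, and the list kept its call without that tumour; without EV rats 2 and 3 together its median was 0.53. Among 8 dendritic and mast cell markers, Xcr1 (-1.20 ± 0.17, detected in 2 of 6 EGFRvIII tumours) and Clec9a (-1.15 ± 0.17), both of cross-presenting dendritic cells, and Flt3 (at least 1.13-fold lower) were the 3 lower genes, and 1 was higher. The list did not pass (adjusted p = 0.196, and 0.0295 without EV rats 2 and 3). These 2 tumours had its lowest EV scores (centred, -0.24 and -0.42), so leaving them out favours a fall.

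**Figure D3:**
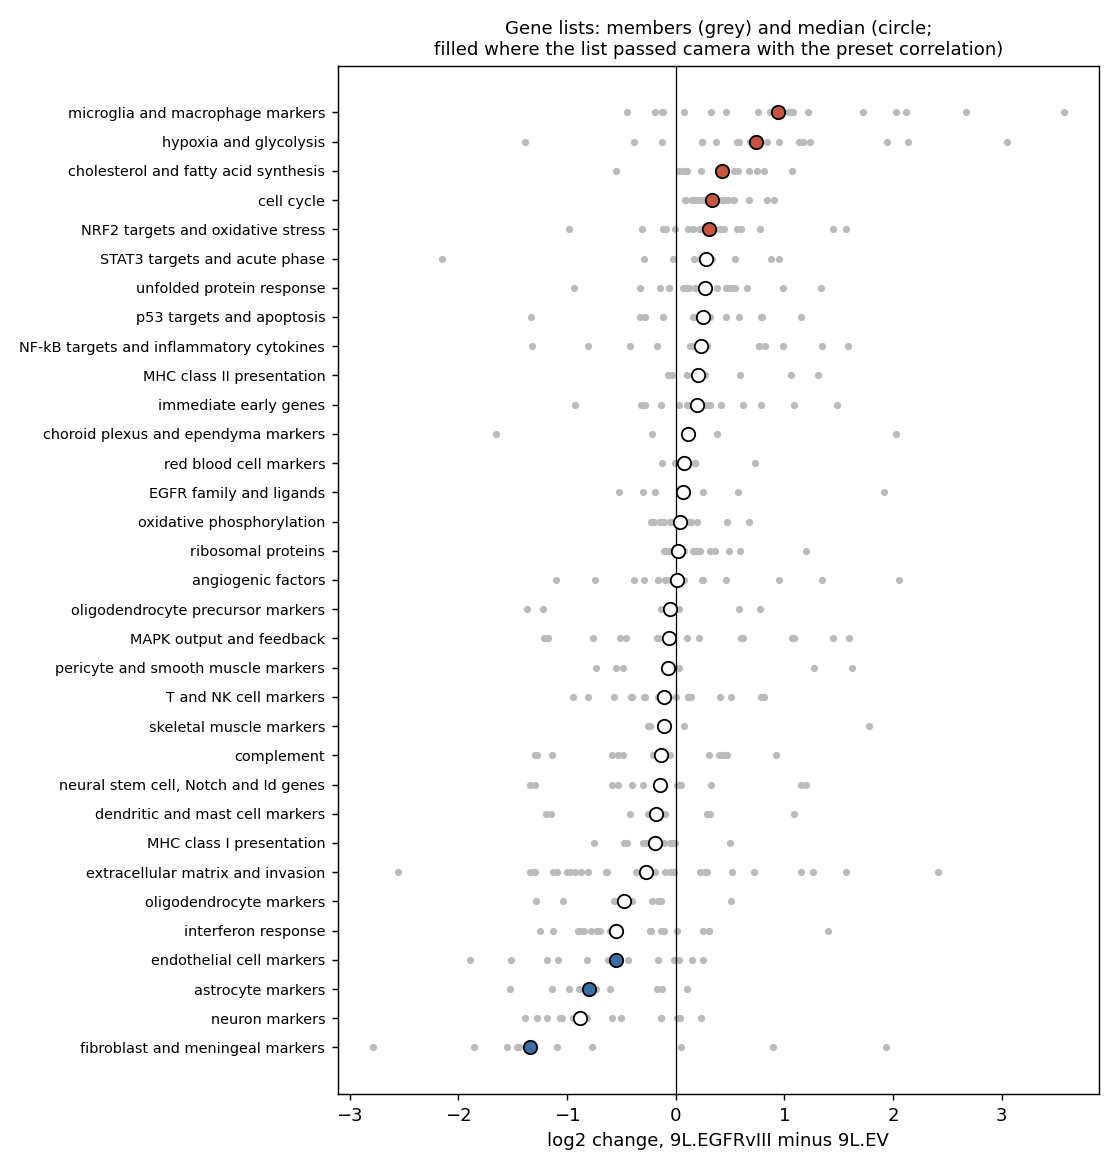
Log2 change (EGFRvIII minus EV, x axis) of each measured member of the 33 tested gene lists, 1 point per gene, with a circle at each median, filled where the list passed at the preset correlation. Hypoxia and glycolysis lie at a median of 0.74 and fibroblast and meningeal markers at -1.34.

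Endothelial markers were lower: of 13, 6 passed, 0 were higher and 7 were not called, and adjusted over the list alone 7 were lower. The brain endothelial transporter Slco1c1 fell (-1.89 ± 0.42, adjusted p = 0.00607), as did Plvap (-1.52 ± 0.42), the tight junction gene Cldn5 (-1.18 ± 0.26) and Emcn (-1.08 ± 0.28), and the list had a median of -0.55 (adjusted p = 0.0405, and 0.602 with an estimated correlation). Its adjusted p was 0.0528 without EGFRvIII rat 3. Of 12 fibroblast and meningeal markers 6 were lower, including Mgp (-1.55 ± 0.39) and Ogn (-1.46 ± 0.36), 2 were higher, including Dpt (1.94 ± 0.35), and 4 were not called; adjusted over the list alone, 7 were lower and 2 higher. The list had a median of -1.34 (adjusted p = 0.0423, and 0.850 with an estimated correlation), and its adjusted p lay between 0.0565 and 0.0925 without any one of EV rats 2 and 4 or EGFRvIII rats 2 to 5. Without EV rats 2 and 3 together its median was -0.89 (adjusted p = 0.0685). Astrocyte markers had a median of -0.80 (adjusted p = 0.0411, and 0.850 with an estimated correlation), with the gap junction gene Gja1 (13.08 ± 0.08 against 12.26 ± 0.18, adjusted p = 3.8e-05) and Clu (-0.89 ± 0.24) lower, 0 higher and 9 not called of 11, also adjusted over the list alone. EV rat 2 held far more of these markers (mean 10.65, against 7.97 in the other 5 EV tumours), and without it the list had a median of -0.35 and an adjusted p of 0.288. Without any one of EV rat 4 and EGFRvIII rats 2 to 5 it lay between 0.0532 and 0.0805.

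Neuron markers had a median of -0.88 and 0 of 17 called by limma, with 1 at an unadjusted p under 0.05. EV rat 2 and EGFRvIII rat 1 lay above the rest of their groups in them, by 2.72 and 2.04 (list adjusted p = 0.196). Without EGFRvIII rat 1 or EV rat 6 that adjusted p was 0.0220 and 0.0491. Among 12 oligodendrocyte markers Enpp2 was lower (-1.04 ± 0.25) and Aspa higher (0.51 ± 0.12; list adjusted p = 0.387). Of 6 oligodendrocyte precursor markers, Pdgfra (-1.37 ± 0.21) and Vcan (-1.22 ± 0.12) were lower and Cspg4 higher (0.78 ± 0.17; list adjusted p = 0.401). Of 8 pericyte and smooth muscle markers Anpep (1.63 ± 0.22) and Des (1.27 ± 0.20) were higher, 2 in all, with 2 higher and 1 lower adjusted over the list alone (median -0.07, mean 0.13, camera direction upward, adjusted p = 0.792). Of 5 choroid plexus and ependyma markers 2 were higher, including the water channel Aqp1 (2.03 ± 0.45), and 1 was lower, Rarres2 (-1.65 ± 0.21; list adjusted p = 0.889).

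Interferon response genes had a median of -0.55, with Ifi44 (-1.13 ± 0.27) and Ifit2 (-0.90 ± 0.25) among 3 lower and Oasl (1.40 ± 0.29) the 1 higher of 22. The list did not pass (adjusted p = 0.196), but its adjusted p was 0.0294 without EGFRvIII rat 6 and 0.0320 without EV rat 3. No gene was called by limma among 23 T and NK cell markers (adjusted p = 0.792) or 14 genes of MHC class I presentation (adjusted p = 0.401), with 1 each at an unadjusted p under 0.05. Without EV rats 2 and 3 both lists passed downward (median -0.77 and -0.60, adjusted p = 0.0159 for each). Those tumours had the lowest EV scores in both lists (centred, -0.67 and -1.85 in T and NK cell markers, -0.51 and -0.68 in MHC class I). Leaving them out raises the EV mean, so these passes give no evidence of their own for a fall. Of 9 genes of MHC class II presentation 2 were higher (adjusted p = 0.407). Of 12 STAT3 targets 2 were higher, including Socs3 (0.95 ± 0.19), with 2 higher and 1 lower adjusted over the list alone (list adjusted p = 0.196). Of 16 NF-kB targets 3 were higher, including the chemokine Cxcl1 (1.34 ± 0.24; list adjusted p = 0.267, and 0.0181 with no filter on dim probes).

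Of 12 p53 targets and apoptosis genes 3 were higher, Gadd45a (1.15 ± 0.20), Phlda3 (0.79 ± 0.14) and Cdkn1a (0.79 ± 0.19), and Sesn1 was lower (-1.33 ± 0.15); adjusted over the list alone, 4 were higher and 1 lower (list adjusted p = 0.397). Of 19 genes of the unfolded protein response 5 were higher, including the asparagine synthetase Asns (1.34 ± 0.23), and 1 was lower, the chaperone Dnajb9 (-0.93 ± 0.17); adjusted over the list alone, 6 were higher and 1 lower (list adjusted p = 0.122, 0.0281 after median scaling and 0.0444 with no filter on dim probes). Of 20 oxidative phosphorylation genes 2 were higher and, adjusted over the list alone, 0 (list adjusted p = 0.780). Of 23 ribosomal protein genes 3 were higher, including Rpl5 (2.30-fold; list adjusted p = 0.281, and 1.5e-04 after median scaling). Of 7 red blood cell markers the transferrin receptor Tfrc was higher (0.73 ± 0.18; adjusted p = 0.407), and of 5 skeletal muscle markers the muscle enolase Eno3 (1.78 ± 0.21; median -0.11, mean 0.25, camera direction upward, adjusted p = 0.841). Of 4 measured neutrophil markers 1 was higher, and of 3 B cell and plasma cell markers 0 were called over all genes and 1 was higher adjusted over the list alone; neither list was tested. In the lists for which no separate count is given, the counts adjusted over the list alone were those over all genes.

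In total 8 of the 33 lists passed, 5 upward and 3 downward, and with an estimated correlation 0 passed, with 2 at an unadjusted p under 0.05. Only 3 to 5 lists passed without any one of EV rat 2 and EGFRvIII rats 2, 3 and 5, and at least as many lists as the real 8 passed in 60 of 100 splits of the 12 tumours into 6 and 6, the real one included.

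**Figure D4:**
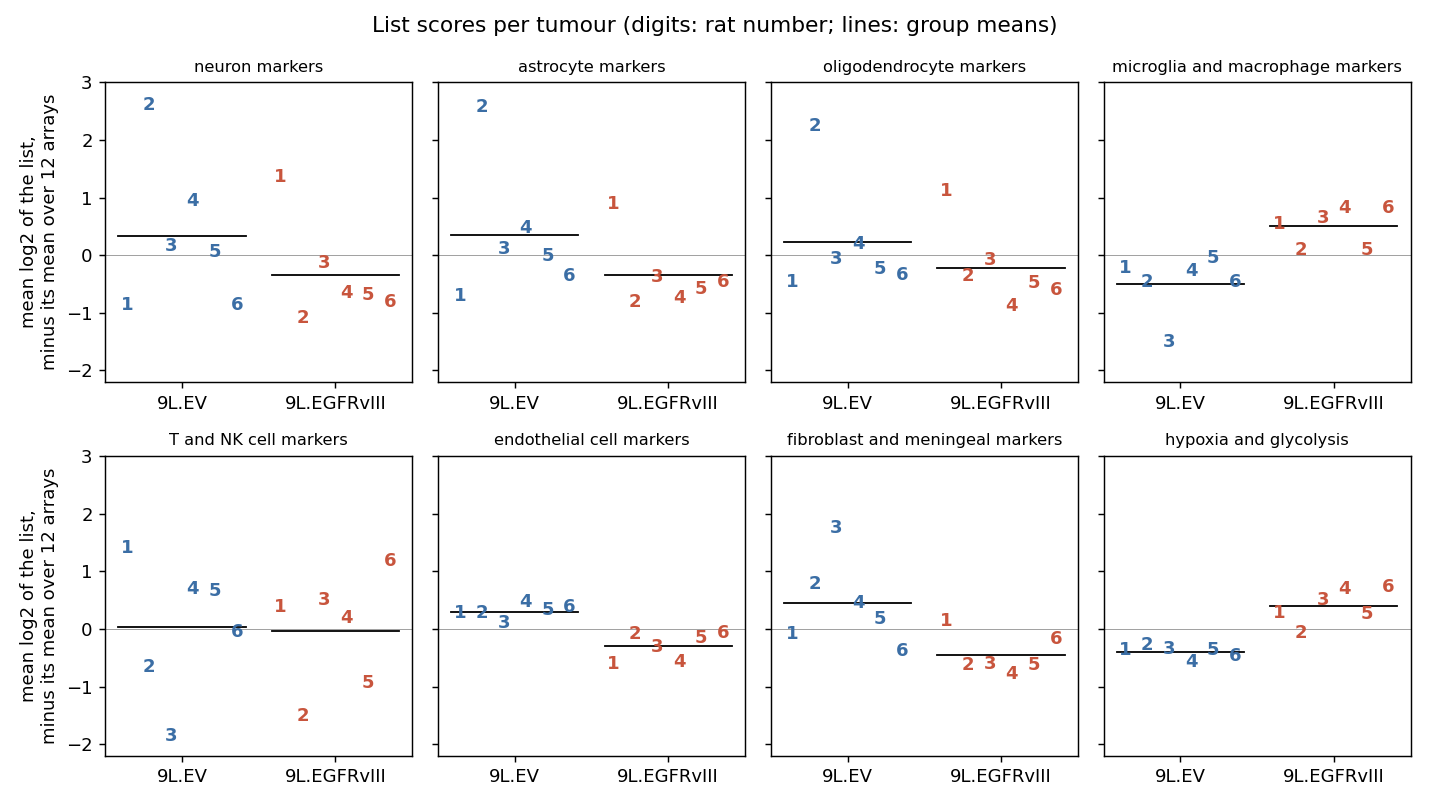
Mean of the centred log2 values of 1 gene list per panel in each tumour, 1 digit (the rat number) per tumour and a line at each group mean. EV rat 2 and EGFRvIII rat 1 stand above their groups in the brain cell markers, and EV rat 3 below its group in the macrophage markers.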

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

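The tests on brain tissue in EV rat 2, and those on less brain tissue in the EGFRvIII pieces and on an unchanged macrophage profile, were chosen after the result had been seen. In each group of 6 tumours, list means, the values of named genes and array measures of signal and detected probes were searched for 1 tumour far from the other 5 (Dixon's gap test). This marked 30 of 288 groups, where chance marks about 1 in 20, or 14.4. Many named genes are members of the lists, so the groups are not independent and 1 tumour can be marked many times. Of the 30, 12 lay in EV rat 3 and 5 in EV rat 2. Values are log2, with the mean of the other 5 tumours of the group after each.

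EV rat 3 was high in immediate early genes (8.62, others 8.0) and in extracellular matrix genes (10.23, others 9.73), and low in oxidative phosphorylation (10.42, others 10.76), MHC class II presentation (8.64, others 10.35) and macrophage markers (6.74, others 7.96). Among single genes it stood apart in Ogn (12.01, others 9.79), Ccn1 (9.45, others 6.40), Msmo1 (11, others 10.17), Spry4 (7.94, others 6.83), Cox5a (9.92, others 10.94) and Sdhb (9.81, others 10.74). Its value for Capn8 (4.61, others 4.32) was marked too, but the gene was detected in 0 of 6 EV tumours and this is background. EV rat 2 was high in astrocyte (10.65, others 7.97), oligodendrocyte (9.01, others 6.58) and oligodendrocyte precursor markers (8.84, others 7.82) and in Sesn1 (9.47, others 8.70), and low in the unfolded protein response (9.18, others 9.66). EV rat 1 was high in angiogenic factors (7.88, others 7.35) and Pgf (7.93, others 7.13), EV rat 5 in Mcemp1 (5.58, others 4.37 and under the detection floor) and EV rat 6 in pericyte markers (6.59, others 6.10).

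Among EGFRvIII tumours, rat 1 was high in astrocyte markers (8.96, others 7.47) and rat 2 in Ccn1 (9.66, others 8.14). Rat 4 was high in Phlda3 (9.66, others 9.14) and low in Enpp2 (8.50, others 9.34). Rat 6 was high in Plvap (8.31, others 6.37), Eno1 (8.88, others 8.18) and Id2 (11.64, others 10.80), and low in Cox5a (10.92, others 11.55) and Cspg4 (6.96, others 7.88).

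The brain markers of EV rat 2 may come from brain tissue around the tumour in its piece. Its neuron, astrocyte and oligodendrocyte scores lay 3.57, 5.92 and 9.41 SD above the other 5 EV tumours, and abundant markers rose with them, as Nrgn (11.86 against 8.04) and Mbp (9.94 against 6.36). Of the marker lists, astrocytes and oligodendrocytes each share 1 gene with another list and neurons 0, and Gja1 was as high in the other EV tumours (13.08 in both). A swapped label is argued against, since in 16 of 16 genes with the largest change EV rat 2 lay nearer to the EV mean. No biological explanation was tested.

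Macrophage markers were higher as a list in EGFRvIII tumours at the preset correlation, with an adjusted p of 0.850 at an estimated one. EV rat 3 alone is argued against, since 100% of the 8 called markers were called without it. Less brain tissue in the EGFRvIII pieces as the whole cause was tested with brain markers as a covariate. The score change stayed at 100.1% of its size (1.00 ± 0.28 SE, lower end of the 95% interval 0.36). A whole cause leaves no change, so the positive interval argues against it, as far as the markers measure brain tissue. The single tumour EGFRvIII rat 1 went the same way. Its brain score (8.16) lay above 5 EV tumours, and its macrophage score (8.79) above the highest EV tumour (8.21). The interval did not clear 50% of that size, a bound of the prediction, so less brain tissue as part of the cause stays open. The list passed with the covariate (camera adjusted p = 7.9e-04 at the preset correlation). At that correlation, splits that ignore the groups often gave as many lists as the real one. Those splits count lists and test no single list, so this pass is given no weight either way. For more macrophages with an unchanged profile, each member was set against the median level of the list on each array, and 9 of 20 departed. Mrc1 (change 3.57 ± 0.45 SE) and Trem2 (2.67 ± 0.21) lay above it. Aif1, Ccr2, Cd4, Cx3cr1, P2ry12, Ptprc and Tmem119 lay below it, and all were named here after their values were seen. The 7 below did not themselves pass over all genes, with changes of -0.44 (Tmem119) to 0.47 (Ptprc), and P2ry12 and Tmem119 are known from resident microglia. Members that come partly from cells whose number did not change would also lie below the median. The test therefore cannot decide on more macrophages with an unchanged profile, which stays open. A macrophage population in another state, a change in both number and state, or expression of these genes by the tumour cells stays open too.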

How the results depend on the processing

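Leaving out 2 or 3 arrays and adjusting for brain markers were chosen after the data had been seen; the other alternatives were planned. Of 107 named genes, 77 were called in every alternative that tested them and 20 lost their call without at least 1 tumour; no gene or list reversed among called results. Leaving out 1 tumour gave 1959 to 2504 genes (996 to 1305 higher and 963 to 1199 lower) and 3 to 9 lists, with 3 without EGFRvIII rat 3, 4 without EGFRvIII rat 2 or 5 and 5 without EV rat 2. Median scaling in place of quantile normalization called 2119 genes higher; the cholesterol list then had an adjusted p of 0.0986 (0.00684 to 0.0986 over its alternatives). A minimum fold of 1.2 left 786 genes (446 higher, 340 lower) and one of 1.5 left 162 (96 and 66), fewer by construction. Using the rat number as a block gave 1817 genes and 8 lists. Brain markers as a covariate gave 2326 genes and 5 lists; the cause was not tested. Without EV rats 2 and 3 and EGFRvIII rat 1, 2061 genes passed, 1789 of them shared with the full set, and 11 lists, among them interferon response (median -0.97, adjusted p = 0.00122; 0.00122 to 0.501 over its alternatives), T and NK cell markers (median -0.86, 0.0127; 0.0127 to 0.984) and MHC class I (-0.69, 0.00780; 0.00780 to 0.778), all downward; these 3 also passed with array weights (0.00171, 0.0204 and 0.0139). EV rats 2 and 3 were the lowest EV tumours in the interferon, T and NK cell and MHC class I lists, so leaving them out favours a fall. Estimated correlation left 0 lists with camera (2 at an unadjusted p under 0.05), and fry called 4 lists by direction and 25 in either direction, a question that does not set a list against other genes. The 4 were hypoxia and glycolysis, NRF2, endothelial and macrophage lists (fry adjusted p = 5.2e-04, 0.00364, 0.00946 and 0.0275). In each of these 4 the list scores of the groups did not overlap. The hypoxia, cell cycle and macrophage lists passed in 27 of 27 alternatives of processing and samples, with adjusted p up to 6.2e-05, 0.0159 and 0.0170; endothelial passed in 25, NRF2 in 24, cholesterol in 19, fibroblast in 17 and astrocyte in 16. The macrophage median fell to 0.53 without EV rats 2 and 3, 0.54 with array weights and 0.45 without the 3 tumours, the cholesterol median was 0.24 with no filter, and the astrocyte median was -0.12 with the brain covariate, -0.28 without EV rats 2 and 3 and -0.49 with array weights. Signal over background limits the lowest values: Nppb and Capn8 in EV and Flt3 in EGFRvIII tumours were detected on 0 of 6 arrays, so their folds are bounds, and 17 other named genes were detected on some arrays of a group; with values raised to the floor 0 changed direction.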

Other observations

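The correlations of list scores, and the window and run of neighbouring genes against random orders, were chosen after the result had been seen. The adjustment over 15 relations does not cover the choice of the pairs of lists. The other tests on neighbours were added once that pattern had been noticed, and only the splits of the tumours were set before. T and NK cell markers did not pass as a list with all 12 tumours, though they did in 3 of 27 alternatives, and varied between tumours together with interferon genes. Across the 12 tumours the scores correlated at r = 0.954 and rho = 0.958 (permutation p = 1e-05 for both, the smallest that 100000 resamples allow, 7.5e-05 after adjustment over 15 relations), and r was 0.952 without the 2 tumours farthest out. Within EV tumours r was 0.964 (exact permutation p = 0.00278, adjusted 0.00833; rho = 1.00) and within EGFRvIII tumours 0.986 (exact permutation p = 0.00556, adjusted 0.0119; rho = 0.943, exact p = 0.0167), and without the 2 farthest r was 0.990 and 0.985. MHC class I genes followed T and NK cell markers in the same way, at r = 0.946 and rho = 0.937 over all tumours (permutation p = 1e-05). In EV tumours r was 0.967 (exact permutation p = 0.00556, adjusted 0.0119) and in EGFRvIII tumours 0.951 (exact permutation p = 0.00833, adjusted 0.0156), with rho = 0.943 in both. Without the 2 tumours farthest out r was 0.952 over all tumours, 0.982 in EV and 0.863 in EGFRvIII tumours. T and NK cell markers hold 1 gene of another list, Ccl5, and interferon and MHC class I genes hold 0.

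Macrophage markers against T and NK cell markers gave r = 0.531 over all tumours (permutation p = 0.0752, rho = 0.343, p = 0.274), and r was 0.256 without the 2 tumours farthest out. The macrophage scores of the groups lay apart (EV up to -0.05, EGFRvIII from 0.08), so the shift between groups enters the values over all tumours. Within EV tumours r was 0.888 (exact permutation p = 0.025, adjusted 0.0417; rho = 0.771, exact p = 0.103), and 0.805 without the 2 farthest. Within EGFRvIII tumours r was 0.917 (exact permutation p = 0.0472, adjusted 0.0708, rho = 0.829, exact p = 0.0583). Without the 2 tumours farthest out in T and NK cell markers it was 0.363, over too few tumours to tell what it rests on. The same limit holds for every value within a group, also the high ones, from which the 2 farthest tumours were left out. Neuron markers against T and NK cell markers gave r = -0.07 over all tumours (permutation p = 0.838; rho = -0.06, p = 0.852), -0.34 in EV and 0.358 in EGFRvIII tumours (exact permutation p = 0.519 and 0.494).

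Tested genes that follow each other in the GRCr8 assembly, called neighbours here, changed together, and genes that were not tested may lie between them. The longest run held 9 neighbours called higher, Camkmt, Prepl, Slc3a1, Ppm1b, Lrpprc, Dync2li1, Plekhh2, Thada and Zfp36l2, with a median log2 change of 1.41; these genes, named after their values were seen, include Prepl, a peptidase (2.44, 5.44-fold), and Lrpprc, which stabilises mitochondrial transcripts (1.93). Another region of 15 genes held 8 higher, among them Stom (2.88), Rab14 (1.74) and Ndufa8 (1.53), and 2 lower, and a further one of 12 genes held 8 lower, among them Zfp36l1 (-1.05), Dcaf5 (-0.98) and Pigh (-0.94).

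Chance order is argued against: over 8373 ordered genes the largest median of 11 neighbours was 0.852, above 0.747, the 95th percentile of 1000 random orders, and the run of 9 exceeded the longest random run of 7 (p = 0.001, the smallest these random permutations of the order allow). Families of near-identical neighbours are argued against, since without genes sharing a symbol stem the window stayed at 0.852 against 0.736. The mix of cells stays open and cannot be told apart: with brain, macrophage, T and NK cell and fibroblast scores as covariates the 27 called genes of the run and regions had 138% of their median change (1.18, median SE 0.41), but 2 of the 27 stayed past the threshold at 6 residual degrees of freedom, too loose to exclude it. A gain or loss of a chromosome segment that the lines do not share may be involved but cannot be told apart either: 60%, 85.7% and 100% of the 15, 14 and 12 genes in the 3 regions moved their region's way, where 80% was the bound set for it, dim and bright genes differed by 1.25, 0.92 and 0.01, where 0.3 was the bound, and regions picked for moving together favour a high share. This is a hypothesis found and tested on the same data, and the 1 line that the labels name per group cannot separate a difference between lines from EGFRvIII.

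Of 100 splits of the tumours into 6 and 6, drawn from 462, only 1, the real one, gave 2519 genes, while the highest of the other 99 gave 0 by limma, with up to 2287 at an unadjusted p under 0.05 (median 419), so chance can be excluded for the gene count. For the number of lists chance cannot be excluded: 60 of 100 splits gave at least the 8 lists of the real one, and the highest other gave 15. The splits count lists and test no single list.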
